A study of Mus musculus with 6 samples.

How the data were processed

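Microglia, about 1000 FACS-sorted cells per sample, came from C57BL/6 mice at postnatal day 42, with 3 wild-type and 3 Lyl1 knockout samples. Per the labels' protocols, first-strand cDNA was made from 0.3 to 1 ng of total RNA with a SMARTer Ultra Low kit and amplified over 14 or 15 PCR cycles. Nextera XT libraries were then built from 150 pg of cDNA and sequenced on a HiSeq 1000 as single reads of 50 cycles. The kit does not mark strand, so reads from overlapping genes on opposite strands cannot be told apart. Neither cDNA step counts molecules, so reads that are PCR copies of 1 molecule are counted separately. The labels do not say which marker combination the sorting gate used.

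The deposited values are raw counts of reads per gene symbol, not normalized, for each of the 6 samples. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2b, Subread, featureCounts 1.5.1 and limma 3.28.21 and the mouse build GRCm38, with no role or order for any of them. The annotation and the strand setting of the counting are not given in the sources used here. The table holds 48679 entries, of which 92 are ERCC spike-in sequences and 48587 are genes. The spike-ins were left out of library sizes and tests, and 22005 genes had at least 1 read. Spreadsheet software had turned 14 gene symbols into dates, and these entries were kept under the names they have. Total counts ran from 12753945 to 27378614 per sample.

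Counts were analysed in R 4.3.3. Genes were kept by edgeR 4.0.16 filterByExpr with its default minimum count of 10 and minimum total of 15, which left 10394 genes, and libraries were scaled by TMM. Levels are given as TMM-scaled CPM (counts scaled to a common library total), as mean ± SD over 3 samples. Knockout was compared with wild type by edgeR's quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit held the genotype alone. Log2 fold changes are knockout over wild type, with the standard error of the fit. A count of 0 in a library allows up to 3 reads, which is 0.104 to 0.264 CPM here. This floor covers counting error only.

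Before the data were examined, 35 gene lists with 1119 members in all were fixed. Of these members 1116 were found in the table, 5 of them under another symbol. Lists with at least 5 tested members, 28 in number, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera asks whether a list's genes stand apart from the other genes. Estimating the correlation makes camera stricter even where the estimate is low. For ribosomal protein genes, with an estimate of 0.00676, its unadjusted p rose from 0.0870 to 0.138. A call lost in that setting therefore does not show that genes varying together were the reason. Beside camera at the preset correlation stand camera with the correlation estimated from these libraries, and fry. Fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. The other 7 lists had fewer than 5 tested members. Medians of the called lists were also set against 10000 random lists matched on transcript length and level, with their central range from the lowest to the highest 2.5%, a comparison added after the data were seen except for oxidative phosphorylation. For the medians per library, log2(CPM + 1) of each member was set against its wild-type mean.

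The rule for the genes named in the text was fixed at the same time. It took Lyl1, then up to 12 genes in each direction with the smallest p among those past the threshold. If fewer than 5 genes passed, it took the 10 genes with the smallest unadjusted p and a mean of 5 CPM or more in at least 1 genotype. It also took up to 3 tested members of each list with the smallest p, 6 microglia markers, Xist and Ddx3y per library, and the most abundant tested member of each list of another cell type. Gene models without a proper symbol were not named. The rule gave 107 genes, of which 1 microglia marker is not reported here. Which of them to describe in words was decided after their values were seen, and a gene outside the rule is said to have been chosen in the same way. Gene positions are those of GENCODE M21 on GRCm38, in which 97.2% of the tested symbols had an entry. Overlaps between genes were read from their start and end, and whether exons overlap was not checked. Some named genes have such an overlap that is not mentioned with them, Csf1r, P2ry12 and B2m among them.

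The count and list tests were tested on simulated data drawn for the 10394 genes at the real means and library sizes, with 200 genes changed. With a dispersion of 0.05, edgeR recovered 43 of 67 genes changed 2-fold, 67 of 67 changed 4-fold and 66 of 66 changed 8-fold, with 8 false calls. With the dispersions observed here it recovered 0 of 67, 0 of 67 and 1 of 66, with 0 false calls. DESeq2 1.42.0, which on the real data left the adjusted p of 8889 of 22005 genes undefined, recovered 0, 7 and 17 of the same genes and made 162 false calls. A shifted list gave an unadjusted camera p of 0.000748 and an unshifted list one of 0.589. Simulated genes were drawn independently, so these list values do not show how camera behaves when a list's genes vary together. In the real data the estimated correlation was 0.333 for immediate-early genes and 0.0517 for oxidative phosphorylation genes.

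The alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling, no filter, and a filter of 5 CPM in 3 libraries. Among tools they were DESeq2, limma-voom with and without sample weights, robust dispersions, and a test against a 1.5-fold change, besides an adjusted p under 0.1. The fit was also changed by the replicate number as a block, Xist or depth as a covariate, and each library left out in turn. The settings chosen after seeing the data are given with the closing observations. Libraries of 1 genotype were checked for duplicates by a chi-square of their counts, and every pair differed by a chi-square per degree of freedom of 245 or more, far above the counting noise.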

Results

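Microglia, the resident macrophages of the brain, were sorted from wild-type mice and from mice without Lyl1 at postnatal day 42, and their polyadenylated RNA was sequenced, with 3 samples per genotype. Lyl1 is a basic helix-loop-helix transcription factor of blood-forming cells, and the series sets out to describe what its loss does to microglia, with neuropsychiatric disorders in its title. Total counts were 12753945, 27378614 and 19632530 for wild-type samples 1 to 3 and 22259533, 19205948 and 27305558 for knockout samples 1 to 3. Between 12827 and 15652 genes were detected per sample. Wild-type sample 3 and knockout samples 2 and 3 had the most, with 15652, 14923 and 15531, against 13045 and 12827 in wild-type samples 1 and 2 and 13085 in knockout sample 1. The labels do not state that the samples came from separate animals. All p-values thus measure the spread between these samples, which may be technical in part or, in wild type, in full. Xist was at 349 and 412 CPM in knockout samples 1 and 3 and at 0.203 CPM in knockout sample 2. Kdm5d, on the Y chromosome, lay the other way. The knockout samples thus did not all come from 1 animal.

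The spread between samples depended on the level of the gene. Among the 97 tested genes at 1000 CPM or more, the median coefficient of variation was 17.5% in wild type and 10.7% in knockout. Among the 4474 genes at 10 to 50 CPM it was 98.4% and 67.8%, and 48.1% of those genes had 3 reads or fewer in at least 1 sample. The common biological coefficient of variation was 1.27. Across genes with a mean of at least 20 CPM, log2 levels correlated with r of 0.333 between wild-type samples 1 and 2 and of 0.682 between knockout samples 2 and 3, while wild-type sample 3 and knockout sample 3 gave 0.809. These correlations run over genes, which are not independent replicates.

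The targeted gene was lower in every knockout sample but was not absent. Lyl1 (ENSMUSG00000034041.4, GRCm38 chromosome 8, 84701457 to 84704715, plus strand, 4 annotated exons) had 683, 1399 and 839 reads in wild type and 205, 237 and 410 in knockout. That is 51.9 ± 10.6 CPM against 11.8 ± 2.63 CPM (SD, n = 3 each), 4.41-fold lower. The log2 fold change was -2.14 with a standard error of 0.98, and the edgeR test gave adjusted p = 0.9999. The exact 2-sided permutation p was 0.1, the smallest that 3 against 3 samples allow. DESeq2 on all genes with a read did call Lyl1, at a log2 fold change of -2.18 (adjusted p = 0.0115), and DESeq2 on the genes edgeR tested did not, at -2.22 (adjusted p = 0.156). The counts are per gene, so reads from parts of Lyl1 that the targeting left in place are included. Nfix overlaps Lyl1 on the opposite strand, and reads from any shared exon part could be counted for Lyl1 or lost to both.

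Of 10394 genes tested, edgeR called 0 higher and 0 lower in knockout microglia. At an unadjusted p under 0.05 there were 121 higher and 174 lower genes, 295 together, where 519.7 would be reached by chance. The count was above chance without wild-type sample 3 (860 higher and 298 lower, 1158 of 11061 against 553 by chance). It was also above chance with limma-voom (663), with edgeR's newer dispersions (709), with DESeq2 on the genes edgeR tested (626 against 497), with no filter (1663 against 1100) and at 100 CPM or more (125 against 86.2), and below it in the other settings. Without knockout sample 1 or 2 the lower genes numbered 95 and 93. Without wild-type sample 3, the wild type was left with the samples with the fewest genes detected, 13045 and 12827. Some splits of all 6 samples that mix the genotypes gave more genes at an unadjusted p under 0.05 than the 295 for genotype. Wild-type sample 3 with knockout samples 1 and 3 against the rest gave 538, and with knockout samples 2 and 3 it gave 532. All remaining mixed splits gave fewer than 295, from 134 to 291. They too stayed under 519.7, so a count below that value is not particular to the genotype. The balance of directions depended on the scaling and the fit, with 133 higher and 99 lower under upper-quartile scaling, 139 and 124 under library size, 98 and 73 with the replicate block, 72 and 286 with Xist as a covariate and 194 and 158 with depth as a covariate. The genotypes did not overlap for 621 higher and 539 lower genes, 11.2% of those tested, where chance gives 10%. DESeq2 on all genes with a read called 97 higher and 40 lower, and 123 of these 137 had a mean under 1 CPM in 1 genotype. Without the filter on low counts, edgeR called 3 genes higher, Apoe, Ccr6 and Xist, and 5 lower, C1qa, C1qb, C1qc, Fcrls and Def8. Of these, C1qa is named here after its values were seen. Wild-type and knockout C1qa lay at 7615 ± 1380 and 5087 ± 512 CPM.

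Among genes that the rule allows to be named, the 10 with the smallest p are given here, none past the adjusted threshold. They formed a group at a low level or without reads in 1 genotype and a group of moderate differences. Def8 (chromosome 8, 123423527 to 123463270) had 1298, 1070 and 963 reads in wild type and 1, 0 and 1 in knockout, and Slc25a32, a mitochondrial folate carrier, had 722, 2111 and 155 against 1, 0 and 0. In the other direction Ccr6, a chemokine receptor (chromosome 17, 8236043 to 8257141), had 5, 2 and 0 reads in wild type and 4757, 937 and 3232 in knockout. Habp4 had 0, 1 and 0 against 606, 440 and 456, and Zfp788 had 0, 1 and 1 against 893, 131 and 792. Dse, a dermatan sulfate epimerase, had 6, 73 and 60 reads in wild type, a mean of 2.10 CPM, against 81.1 ± 35.5 CPM in knockout. Def8 shares its strand and position with the gene model Gm20388, and Zfp788 belongs to a family of similar zinc finger genes, so both are uncertain.

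The moderate differences among those 10 were all toward lower levels in knockout. Fcgr2b, the inhibitory Fc gamma receptor (chromosome 1, 170958617 to 170976547), was at 546 ± 24.1 CPM in wild type and 238 ± 41.1 CPM in knockout (SD, n = 3 each). Its log2 fold change was -1.20 with a standard error of 0.24 and an unadjusted p of 0.00116. Sec11c, a signal peptidase subunit, was at 482 ± 120 and 194 ± 21.2 CPM, and Ltc4s, the leukotriene C4 synthase, at 311 ± 55.5 and 110 ± 23.3 CPM. Aif1, which encodes the microglial marker IBA1, was at 1152 ± 137 and 646 ± 110 CPM. Fcgr2b and Ltc4s each overlap an antisense gene model. Where exons overlap, its reads could be counted with theirs or lost to both. For all 10 genes edgeR gave adjusted p = 0.9999. DESeq2 on the genes edgeR tested called 34 higher and 18 lower, among them all of these 10 but Aif1. On simulated samples with the spread observed here it made 162 false calls, more than the 52 real calls. Splits of the real samples that mix the genotypes gave from 21 to 293 calls. The simulated number therefore does not say how many of the 52 are false.

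**Figure D1:**
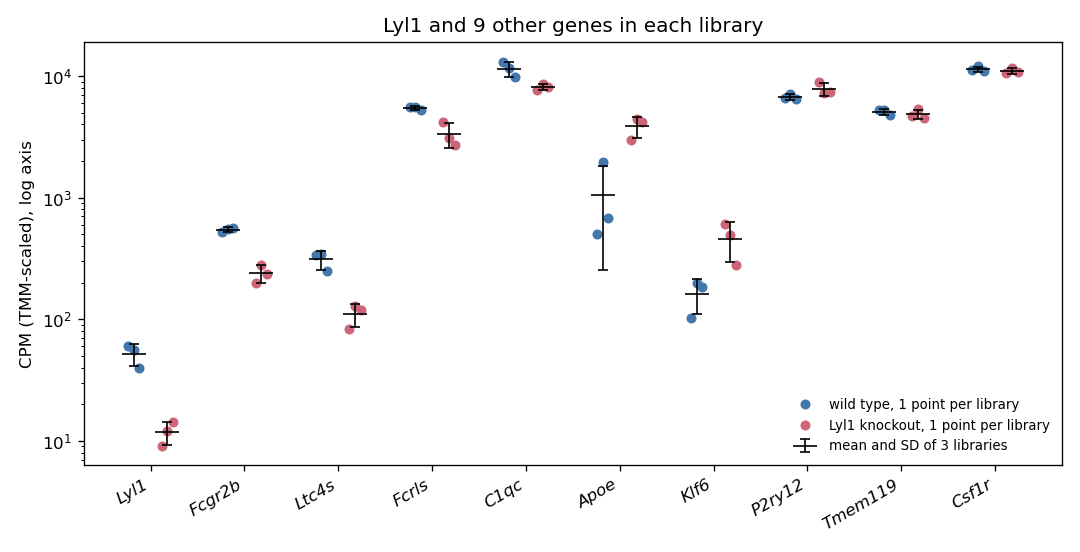
TMM-scaled CPM on a log axis for Lyl1 and 9 other genes, 1 point per sample, with the mean and SD of the 3 wild-type and 3 knockout samples. Lyl1, Fcgr2b, Ltc4s, Fcrls and C1qc lie lower and Apoe and Klf6 higher in all 3 knockout samples, and none passed the adjusted threshold in the test across 10394 genes.

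The markers that define microglia were present at high levels in both genotypes. P2ry12 was at 6729 ± 330 CPM in wild type and 7825 ± 944 CPM in knockout, and Cx3cr1 at 3905 ± 102 and 4247 ± 611. Tmem119 was at 5084 ± 271 and 4842 ± 422 CPM and Csf1r, the CSF1 receptor, at 11351 ± 576 and 11071 ± 596. The log2 fold changes of the last pair, -0.07 and -0.04, turned positive with upper-quartile or library-size scaling. Sall1, a transcription factor of microglial identity, was at 399 ± 20.05 and 565 ± 172 CPM, with 688, 368 and 638 CPM in knockout samples 1 to 3, and its sign turned once Xist was a covariate. Upper-quartile scaling shifts the median log2 fold change of all tested genes by 0.12.

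Of 34 homeostatic microglia genes 20 were lower and 14 higher in knockout, and 5 were lower at an unadjusted p under 0.05, but the list was not called (camera, adjusted p = 0.0540). Among its members Fcrls, an Fc receptor-like protein of microglia (chromosome 3, 87250758 to 87263738), was at 5469 ± 224 and 3328 ± 782 CPM. Of 32 complement and phagocytosis genes 22 were lower and 10 higher, with 8 lower and 1 higher at an unadjusted p under 0.05 (adjusted p = 0.0540). Fcgr2b alone passed when adjusted over the list alone. C1qb and C1qc, subunits of the complement initiator C1q, were at 16992 ± 1680 and 11462 ± 1663 CPM in wild type and at 13041 ± 439 and 8099 ± 447 in knockout. With RLE scaling both lists were called lower, at adjusted p = 0.0195 and adjusted p = 0.0221. Neither was called with upper-quartile scaling (adjusted p = 0.529 and 0.423), with library size (0.325 for both) or with Xist as a covariate (0.377 and 0.945). With a filter of 5 CPM the complement list was called (adjusted p = 0.0355), and in the 3 samples with the most genes its direction turned to up (adjusted p = 0.593). Without wild-type sample 3 both had adjusted p = 0.0328, without knockout sample 1 the homeostatic list had adjusted p = 0.0450, and without knockout sample 2 the complement list had adjusted p = 0.0395.

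Genes of the disease-associated microglia state fell as a list in knockout. Of 29 tested members 23 were lower and 6 higher, with a median log2 fold change of -0.27 (camera, adjusted p = 0.0158; adjusted p = 0.899 with an estimated correlation). That median lay at percentile 18.1 of 10000 random lists matched on transcript length and level, inside their central range of -0.44 to 0.16. Ccl6, a chemokine, was at 499 ± 151 CPM in wild type and 215 ± 47.8 in knockout, Tyrobp at 2627 ± 685 and 1575 ± 298, and Trem2, the lipid receptor that signals through Tyrobp, at 2670 ± 325 and 1950 ± 92.4. B2m was at 3059 ± 635 and 2209 ± 45.6 CPM and the protease Ctsl at 2063 ± 622 and 1403 ± 140. Trem2 is also a member of the homeostatic and complement lists and Tyrobp of the complement list, so these lists are not independent results. Apoe, the lipid carrier whose level rises in that state (chromosome 7, 19696109 to 19699188), lay the other way, at 1044 ± 789 CPM in wild type and 3863 ± 777 in knockout, 3.70-fold higher, with a log2 fold change of 1.89, a standard error of 0.49 and an unadjusted p of 0.00518. No member passed when adjusted over the list alone. The list kept its direction under 19 alternatives but its call under 5 (adjusted p from 0.0110 to 0.899), and with Xist as a covariate it had adjusted p = 0.377. Its call was lost without wild-type sample 1 (adjusted p = 0.126) or 2 (0.114) and without knockout sample 1 (0.122), 2 (0.0546) or 3 (0.150).

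Immediate-early genes, which neurons and immune cells switch on within minutes of a stimulus and which tissue dissociation also induces, rose as a list in knockout. Of 24 tested members 21 were higher and 3 lower, with a median log2 fold change of 0.74 (camera, adjusted p = 0.00151; adjusted p = 0.899 with an estimated correlation). At an unadjusted p under 0.05 there were 6 higher members and 1 lower. The median lay above the central range of random lists matched on length and level, -0.41 to 0.26. The transcription factor Klf6 (chromosome 13, 5861482 to 5870394) was at 161 ± 51.2 CPM in wild type and 460 ± 165 in knockout, Jun at 2044 ± 254 and 3449 ± 1302, Junb at 1016 ± 168 and 1494 ± 192, and Egr1 at 847 ± 54.3 and 1760 ± 1086. The shift was uneven between knockout samples. The median of the members against the wild-type mean was 1.07, 0.79 and -0.16 in knockout samples 1 to 3, and -0.07, -0.08 and 0.03 in wild-type samples 1 to 3. Egr1 was at 2898, 1647 and 734 CPM in the knockout samples. The globins were also uneven between them, with Hbb-bs at 127, 38.2 and 0.0348 CPM and Hba-a1 at 41.4, 13.1 and 0.174 CPM in knockout samples 1 to 3. No member passed when adjusted over the list alone, and adjusted p ran from 1.75e-07 to 0.899 over 19 alternatives. The call was lost without wild-type sample 3 (adjusted p = 0.148), without knockout sample 1 (0.204) and without knockout sample 2 (0.0546), and without knockout sample 3 the adjusted p was 1.75e-07.

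Other inflammation and stress lists were not called. Of 26 inflammatory and NF-kB genes 16 were higher and 10 lower (adjusted p = 0.949), with a median of 0.22, a mean of -0.16 and a test direction of down. Among them Socs3, a brake on cytokine signalling, was at 82.8 ± 27.0 and 228 ± 82.1 CPM and the adhesion molecule Icam1 at 200 ± 23.3 and 316 ± 46.6, while the cytokine Tnf lay the other way, at 47.4 ± 20.1 and 6.84 ± 4.99. Type I interferon genes were split 16 higher to 12 lower of 28, with the chemokine Ccl12 at 191 ± 29.3 and 105 ± 18.5 CPM. MHC class II genes were split 6 to 7 of 13, with a median of -0.05, a mean of 0.10 and a test direction of down. Heat shock genes were split 7 to 12 of 19 and unfolded protein response genes 14 to 12 of 26, the last with a positive median and a test direction of down. Camera gave adjusted p = 0.809 for interferon, MHC class II and heat shock genes and adjusted p = 0.949 for the unfolded protein response. MHC class I genes had 7 higher and 12 lower of 19, with a median of -0.36 (adjusted p = 0.674).

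Nuclear genes of oxidative phosphorylation fell as a list in knockout. Of 75 tested members 59 were lower and 16 higher, with a median log2 fold change of -0.49 (camera, adjusted p = 0.000336; adjusted p = 0.899 with an estimated correlation). The median lay below the central range of random lists matched on length and level, -0.37 to 0.04. Atp5f1, a subunit of ATP synthase, was at 221 ± 73.0 CPM in wild type and 96.8 ± 29.5 in knockout, Cox7b of complex IV at 119 ± 49.7 and 41.3 ± 15.1, and Ndufc1 of complex I at 56.9 ± 35.9 and 8.76 ± 3.35. The members' median against the wild-type mean was -0.29, -0.53 and -0.41 in knockout samples 1 to 3 and 0.00, 0.11 and -0.13 in wild-type samples 1 to 3. Genotypes did not overlap for 15 members, all of them lower, and no member passed when adjusted over the list alone. The call held without any 1 sample (adjusted p from 7.32e-05 to 0.0329) and was lost in genes at 100 CPM or more (adjusted p = 0.198) and in the 3 samples with the most genes (adjusted p = 0.358), within a range of 7.32e-05 to 0.899 over 19 alternatives. With an estimated correlation or with fry none of the 28 lists was called. Camera at the preset correlation was also run, after the data were seen, on splits of the samples that mix the genotypes. The smallest adjusted p of any list was 1.27e-07 with wild-type samples 2 and 3 and knockout sample 3 against the rest. With wild-type samples 1 and 3 and knockout sample 3 against the rest it was 6.71e-05. An adjusted p as small as 0.000336 thus also arose in splits that do not follow the genotype.

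Of 81 cytosolic ribosomal protein genes 49 were lower and 32 higher (median -0.24, adjusted p = 0.348), and of 10 genes of the mitochondrial genome 8 were lower and 2 higher (median -0.30, adjusted p = 0.356). Mitochondrially encoded mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l had 0 reads in all samples. Glycolysis genes were split 11 higher to 10 lower of 21, with a positive median and mean and a test direction of down. Cholesterol synthesis genes were split 9 to 9 of 18 and genes of lipid efflux and its nuclear receptors 7 to 11 of 18. Of 50 lysosomal genes 20 were higher and 30 lower, with a median of -0.08, a mean of 0.03 and a test direction of down. Hexa, a lysosomal enzyme, was at 2379 ± 426 and 1619 ± 111 CPM, and the peptidase Tpp1 at 285 ± 101 and 514 ± 44.6. Each of these last 4 lists had adjusted p = 0.809. Cell division genes had 5 higher and 9 lower of 14 (adjusted p = 0.307), and with depth as a covariate that list was called lower at adjusted p = 0.0266.

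**Figure D2:**
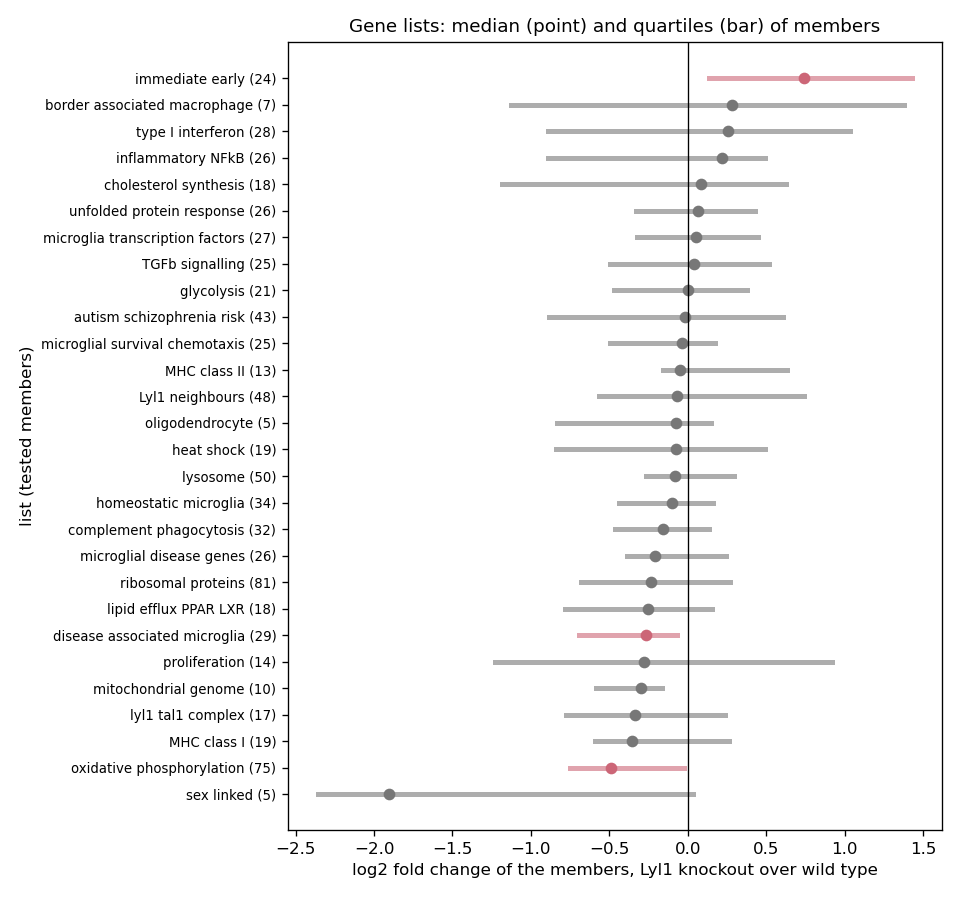
Median (point) and quartiles (bar) of the log2 fold changes, knockout over wild type, of the tested members of 28 gene lists, with the number of members in parentheses and lists with an adjusted camera p under 0.05 in red. Immediate-early genes had a median of 0.74, oxidative phosphorylation genes of -0.49 and disease-associated microglia genes of -0.27.

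**Figure D3:**
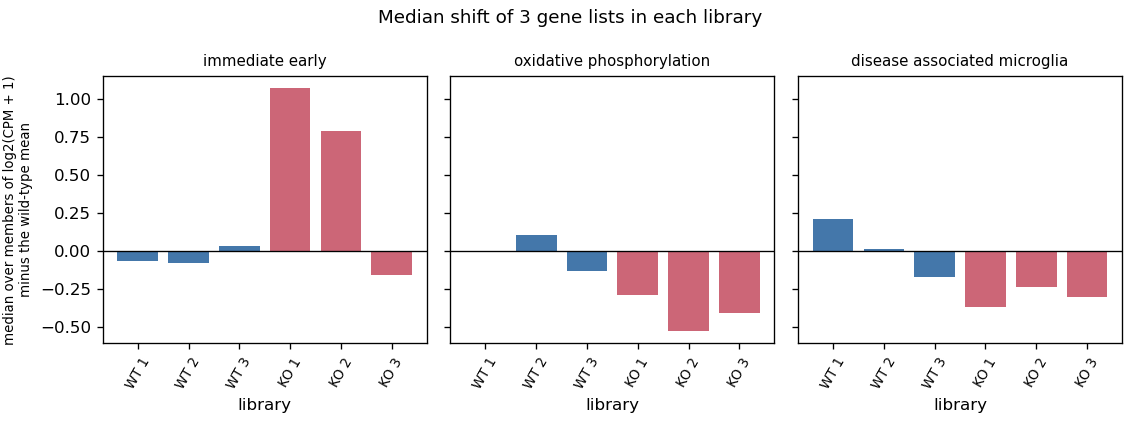
Median over the members of log2(CPM + 1) minus the wild-type mean, for the 3 lists that were called, as 1 bar per sample. The immediate-early bars of knockout samples 1, 2 and 3 stand at 1.07, 0.79 and -0.16, and the oxidative phosphorylation bars at -0.29, -0.53 and -0.41.

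Among Lyl1, its paralog Tal1 and their partners, 10 of 17 tested genes were lower and 7 higher (median -0.33, adjusted p = 0.431). Hhex, a homeobox factor of early blood formation, was at 425 ± 211 CPM in wild type and 249 ± 15.7 in knockout. Transcription factors of microglial identity were split 14 higher to 13 lower of 27, TGF-beta signalling genes 14 to 11 of 25, and survival and chemotaxis genes 10 to 15 of 25, each with adjusted p = 0.809. Of 48 tested genes near Lyl1, between 83566671 and 86885258 on chromosome 8, 22 were higher and 26 lower (adjusted p = 0.809), with a median of -0.07, a mean of 0.01 and a test direction of down. Among these neighbours Prdx2, a peroxiredoxin, was at 143 ± 43.2 and 51.5 ± 11.4 CPM, and it overlaps Junb on the opposite strand.

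Since the series title names neuropsychiatric disorders, genes widely listed for autism or schizophrenia risk were taken as a list. Of 43 tested genes 20 were higher and 23 lower in knockout (adjusted p = 0.923), with a median of -0.02, a mean of 0.08 and a test direction of down, and none passed when adjusted over the list alone. Ddx3x, an X-linked RNA helicase, was at 63.7 ± 17.8 CPM in wild type and 190 ± 132 in knockout. The kinase Dyrk1a was at 83.0 ± 21.4 and 23.7 ± 7.14 CPM and Cul3, a ubiquitin ligase scaffold, at 112 ± 14.4 and 32.4 ± 24.9. Human disease genes that act in microglia had 10 higher and 16 lower of 26 (adjusted p = 0.809), with a median of -0.21, a mean of 0.05 and a test direction of down.

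The samples differed in sex-linked genes. Xist, the RNA of the inactive X chromosome, was at 349 and 412 CPM in knockout samples 1 and 3 and between 0.203 and 1.41 CPM in the other 4. It overlaps the antisense gene Tsix, whose reads could be counted with its own or lost to both where exons overlap. Kdm5d, on the Y chromosome, was at 7.14, 155 and 15.5 CPM in wild-type samples 1 to 3 and 19.6 CPM in knockout sample 2, against 0.0881 and 0.0696 CPM in knockout samples 1 and 3, and Ddx3y was at 1.06, 28.7, 9.44 and 7.57 CPM against 0 and 0.0696 CPM. Of 5 tested sex-linked genes 2 were higher and 3 lower (median -1.90, mean 0.22, test direction down, adjusted p = 0.379), and Xist alone passed when adjusted over the list alone. Xist was thus absent or near 0 in the 3 wild-type samples and in 1 of the 3 knockout samples, so it was not balanced between the genotypes in comparisons of all 6 samples, and a fit with Xist as a covariate rests mostly on knockout sample 2.

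Markers of other cell types were read at levels that differed between samples. In wild-type sample 1 the oligodendrocyte gene Mag was at 178 CPM, the macrophage gene Mrc1 at 95.4 and the endothelial gene Pecam1 at 154, against highest levels of 48.1, 20.1 and 61.5 CPM in the other samples. Border-associated macrophage genes, Mrc1 among them, had a median against the wild-type mean of -1.35, -1.35 and 1.58 in wild-type samples 1 to 3. In wild-type sample 1 Mrc1 was thus high while its list was as low as in sample 2. The genes of that list were split 4 higher to 3 lower of 7, with Stab1 at 398 ± 28.7 and 292 ± 117 CPM. Oligodendrocyte genes were split 2 to 3 of 5, with Trf at 309 and 294 CPM (camera, each adjusted p = 0.809). Too few genes were tested for a list test of monocytes (4, with Gngt2 at 187 and 163 CPM), neutrophils (1, Csf3r, 639 and 546), lymphocytes (3, Ighm, 1045 and 1122), neurons (1, Dlg4, 10.2 and 3.84), astrocytes (1, Slc1a3, 329 and 219), vessel cells (4, Bsg, 742 and 775) and red cells (2, Bpgm, 49.8 and 18.6). The means are of wild type and knockout, in that order. Most listed markers did not pass the filter, with 1 of 16 tested for neutrophils and 3 of 24 for lymphocytes. For neurons 1 of 20 was tested and for astrocytes 1 of 18. Each gene given is the most abundant tested member of its list, so its level does not show that such cells were present. The beta-globin Hbb-bs, whose reads can be shared with its near copies, was at 127 CPM in knockout sample 1 and 38.2 CPM in knockout sample 2 and at most 0.705 CPM in the other samples. Hbb-bs passed when adjusted over the red cell list alone.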

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

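No planned test stands behind the values in this part, which were looked at only after the data were seen. Reads of ERCC spike-in sequences, a signal outside the gene counts, were present in every sample although the labels mention no spike-in. There were 66, 50 and 21 such reads in wild-type samples 1 to 3 and 25, 21 and 25 in knockout samples 1 to 3, each above the 3 reads that a count of 0 allows. They make up between 9.16e-05% and 0.000517% of the counts, too few to scale the libraries. The test for single samples far from their group was not applied, since it needs groups of more than 3.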

How the results depend on the processing

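The settings with only some of the samples (the 3 with the most genes, or the 4 without Xist), with genes at 100 CPM or more, with DESeq2 on the genes edgeR tested and with edgeR's newer dispersions were chosen after seeing the data. With some of the samples, 1 genotype keeps a single sample, which is assumed to vary like the other genotype. With Xist as a covariate the genotype term rests mostly on knockout sample 2, the only knockout without Xist. Lyl1 stayed lower throughout, from -2.30 to -1.98 with 1 sample left out. It passed the threshold with DESeq2 on all genes (-2.18, adjusted p = 0.0115). Counts of called genes stayed at 0 with 1 sample left out and in all other settings except no filter (3 higher, 5 lower), DESeq2 (97 and 40) and DESeq2 on the genes edgeR tested (34 and 18). In the first of these the low genes that were filtered out before enter the fit, with 22005 genes tested instead of 10394. Whether that is what brings the calls was not tested, nor was the cause in the other settings.

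Lists called lower numbered 4 with RLE scaling and at an adjusted p under 0.1, 1 with upper-quartile scaling, library size, no filter, Xist as a covariate or without the Xist samples, 0 at 100 CPM or more, in the 3 samples with the most genes, with an estimated correlation and with fry, and 1 to 4 with 1 sample left out. Lists called higher numbered 2 without the Xist samples, 0 in the 3 samples with the most genes, with an estimated correlation and with fry, and 0 to 2 with 1 sample left out. The 3 called lists kept their direction throughout. All 3 had adjusted p = 0.899 with an estimated correlation, and fry gave 0.787 for immediate-early genes and 0.536 for the other two. In the 3 samples with the most genes, where fewer samples enter, the adjusted p was 0.358 for immediate-early and oxidative phosphorylation genes and 0.593 for disease-associated genes. At 100 CPM or more it was 0.198 for oxidative phosphorylation and disease-associated genes. Disease-associated genes also lost their call with upper-quartile scaling (0.0864), library size (0.0556), no filter (0.147), Xist as a covariate (0.377) and without the Xist samples (0.632). With 1 sample left out the adjusted p ran from 7.32e-05 to 0.0329 for oxidative phosphorylation, from 1.75e-07 to 0.204 for immediate-early and from 0.0355 to 0.150 for disease-associated genes. The cause was not tested.

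Samples with the same replicate number did not deviate together (correlations of 0.00138, -0.0132 and -0.0403 over 6523 genes). This gives no sign that the numbers pair them, but a shared origin weaker than the spread between samples would be missed. With the replicate block Lyl1 was at -2.14, 0 genes were called in either direction, and 1 list was higher and 3 lower, the sex-linked list being added at adjusted p = 0.0331.

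Of 1467 values recomputed for 65 named genes, among them genes given only as levels, 45 changed sign, in 17 genes. Tmem119 turned to 0.068 with upper-quartile scaling, 0.041 with library size, 0.048 with Xist as a covariate, 0.050 at 100 CPM or more, 0.054 in the 3 samples with the most genes and 0.081 without the Xist samples. Csf1r turned to 0.10, 0.073, 0.043, 0.083, 0.055 and 0.063 in the same order and to 0.012 with no filter, and with 1 sample left out it ran from -0.062 to 0.031, the last without wild-type sample 2. With Xist as a covariate and without the Xist samples, Sall1 turned to -0.057 and -0.10 and Xist itself to -1.03 and -1.79, and without the Xist samples Stab1 turned to 0.046. The cause was not tested.

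Among markers of other cell types, Trf turned to 0.025 with upper-quartile scaling, 0.013 with library size and 0.021 at 100 CPM or more, and Bsg to -0.0045 with RLE scaling and -0.0044 with DESeq2 on the genes edgeR tested. Bpgm turned to 0.43 with limma-voom and 0.79 with its quality weights. With depth as a covariate Dlg4 turned to 0.99, Mrc1 to 0.073 and Pecam1 to 0.12, and in the 3 samples with the most genes Dlg4 turned to 6.71, Slc1a3 to 0.19, Mag to 0.35 and Pecam1 to 0.35. Tal1 turned to 0.79 with limma-voom, 0.14 with the replicate block and 1.12 with depth as a covariate. With 1 sample left out, values ran from -1.61 to 0.023 for Tal1, from -5.79 to 2.22 for Dlg4, from -1.22 to 0.37 for Pecam1 and from -0.020 to 0.39 for Ighm, each turning without wild-type sample 1. They ran from -0.38 to 0.083 for Csf3r, from -0.077 to 0.32 for Bsg and from -1.996 to 1.01 for Bpgm, turning without wild-type sample 2, and from -0.44 to 0.060 for Gngt2 and from -0.19 to 0.14 for Trf, turning without wild-type sample 3. The cause was not tested. At 10 to 50 CPM 48.1% of the genes had a sample with 3 reads or fewer.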

Other observations

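The values in this paragraph were chosen after they were seen, and no test beyond that of the genotypes was made. Zfx, an X-linked transcription factor of stem cells, had 42, 55 and 116 reads in wild-type samples 1 to 3 and 545, 629 and 640 in knockout samples 1 to 3, which is 3.70, 2.18 and 5.53 CPM against 24.0, 32.0 and 22.3 CPM. Knockout sample 2, which lacks Xist, had the highest level, and Zfx overlaps an antisense gene model. Tal1, the paralog of Lyl1, was detected in every sample, with 445, 6 and 388 reads in wild type and 356, 60 and 275 in knockout. Lmo2, a partner of both proteins, was at 421 ± 129 CPM in wild type and 296 ± 80.6 in knockout, and Gata2, which acts with them in blood stem cells, had 0 or 1 read in every sample. The alpha-globins Hba-a1 and Hba-a2 were at 41.4 and 32.5 CPM in knockout sample 1 and 13.1 and 11.3 CPM in knockout sample 2, beside the beta-globin in the same 2 samples.

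Of the tests that follow, all were chosen after the result was seen except that of transcript length and level for oxidative phosphorylation genes, which was set before.

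The first pattern is genes with 3 reads or fewer in each sample of 1 genotype and at least 5 CPM in each sample of the other. There were 3 such genes near 0 in knockout, Def8, Immp2l and Slc25a32, and 10 near 0 in wild type, with Habp4, Zfp788, Nod2 and Caprin2 among them, 13 in all, of which Immp2l, Nod2 and Caprin2 are named after their values were seen. If transcripts are lost at random in libraries made from few cells, most of the other 9 splits of the 6 samples should give as many, a bound set after these values were seen, and the highest gave 85. The 4 splits with wild-type sample 3 and knockout sample 3 on the same side, the samples with the most genes detected, gave 32, 42, 84 and 85, while the other 5 gave 5 to 11, all below 13. The higher numbers thus follow these samples, so random loss cannot be told apart from an effect of the genotype on single genes.

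The second pattern is the higher level of immediate-early genes. It was uneven, with a lowest knockout median of -0.16, below all 3 wild-type samples. Knockout samples 1 and 2, which carry the rise, also had the beta-globin Hbb-bs at 127 and 38.2 CPM, against 0.0348 CPM in knockout sample 3. The medians did not follow Xist. Knockout sample 2, without Xist, stood at 0.79, and knockout sample 3, with Xist, at -0.16. Knockout sample 1, with Xist, stood at 1.07, and the wild-type samples, without it, at 0.03 or less. These values argue against sex as the only source of the rise, in knockout samples 2 and 3. A part played by sex cannot be told apart from genotype. The camera adjusted p of 0.00170 with Xist as a covariate rests mostly on knockout sample 2, the only knockout without Xist. A handling response in single samples cannot be told apart from a genotype effect that shows in only some of them, because the uneven medians prompted the idea of handling and so do not test it.

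The third pattern is the lower level of oxidative phosphorylation genes. Their transcripts are short, with a median length of 601 bases against 1289 over all genes. The list's median log2 fold change of -0.49 lay at percentile 0.0700 of 10000 random lists matched on length and level. That is within the lowest 2.5%, the bound set before for a change beyond length and level. The random genes were drawn singly, so lists of genes that vary together could spread more widely than these. The percentile thus does not settle whether length and level are the cause. Knockout sample 2, without Xist, had a median of -0.53, against -0.29 and -0.41 in knockout samples 1 and 3, which have Xist. This is 1 sample, so sex cannot be told apart from genotype for this list. The camera adjusted p of 0.0106 with Xist as a covariate rests mostly on the same sample. Loss of low transcripts cannot be told apart from a real change, because the 25 members at 100 CPM or more had a median of -0.43, at percentile 6.23 of matched lists, between bounds that were redrawn after this value was seen, the first bounds having read it in favour of such loss. A lower expression of respiratory chain genes in microglia without Lyl1 is compatible with these values, but only as a hypothesis. The list's call is lost with an estimated correlation (camera, unadjusted p = 0.0580, adjusted p = 0.899). That setting is stricter in itself, so it does not settle whether the genes' correlation is the reason.

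The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. For genes called higher and for genes called lower, the real split and the highest of the others all gave 0, so that 10 of 10 splits gave as many in each direction. For lists called higher the real value was 1 and the highest other 3, with 7 of 10 splits giving as many, and for lists called lower it was 2 against 3, with 3 of 10 giving as many. DESeq2 on the genes edgeR tested called 52 genes for genotype and 293 for wild-type sample 3 and knockout samples 2 and 3 against the rest, and 5 of 10 splits gave as many. Those 3 samples are also the ones with the most genes detected. Wild-type sample 3 and knockout samples 1 and 3 against the rest gave 258 calls, though knockout sample 1 had only 13085 genes detected. Whether the calls follow the number of genes detected was not tested.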
